A study of Mus musculus with 2 samples.

How the data were processed

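H3K27ac was measured by ChIP-seq in lung tissue of mouse embryos (strain B6NCrl, embryonic day 16.5), per the labels. The labels give 1 group of 2 biological replicates, each a pool of lungs from embryos of both sexes, and no treatment or contrast. The 4 deposited peak lists were the starting point: 1 per replicate, 1 called on both replicates together and 1 of replicated peaks. The deposited readme texts list 1 alignment file and 2 further source files behind the replicate 1 list, 1 alignment file and 1 further source file behind the replicate 2 list, 2 alignment files and 2 further source files behind the pooled list, and 3 peak lists behind the replicated list. The readme texts give mm10 as the build. The aligner, the peak caller, their versions and thresholds, and the rule by which replicated peaks were chosen are not given in the sources used here. Signal tracks were not analysed here.

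Each list has 10 columns in the narrowPeak layout and no header. The fold enrichment of a peak (column 7) is a ratio over a control made by the authors, per the fold-over-control tracks that the deposited readme texts name. The −log10 p-value and −log10 q-value of a peak are those the authors deposited, with no further normalization. The display score and the summit offset in bp that the authors deposited were read and not used for results. The lowest deposited −log10 p-value was about 2.0 in each list (2.03 in the replicated list), and 1267 replicated peaks (1.81%) had a q-value above 0.05. No file gives read counts, so depth per sample is unknown and no value was adjusted for it. Precision is therefore given as exact binomial (Clopper-Pearson) 95% intervals on numbers of peaks or genes, or as the spread of random placements. Odds ratios of sequences and ratios of peak density carry 95% intervals by a normal approximation on the log scale. These intervals cover counting error only. With 2 pools in 1 group, no test between groups of samples was possible, and p-values compare sets of peaks or genes within these lists.

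Peaks on the 21 assembled chromosomes were used, and 9 replicated peaks on other scaffolds were left out. All peak ends lay within the GRCm38 (mm10) chromosome lengths of the reference. Genes, transcripts and TSSs came from GENCODE release M21 on the same build (132629 TSS positions, 21938 protein-coding genes). Coordinates are 1-based. A peak was overlapped when it shared 1 bp or more with a peak of the other list. Random expectations came from 100 placements of the peaks on their own chromosomes outside assembly gaps of 100 bp or more. A peak within 1000 bp of any annotated TSS was TSS-proximal, and the others were exonic, intronic or intergenic by their midpoint. A gene was marked when any part of a peak lay within 1000 bp of one of its TSSs.

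Before the data were examined, 27 gene lists (413 entries, 400 distinct genes, all matched to the annotation), 22 consensus sequences, the tests and 55 of the alternatives were fixed. Marked shares of a list were compared with all other protein-coding genes by two-sided Fisher's exact tests. Distal peaks, more than 1000 bp from every TSS, were assigned by their midpoints to the nearest protein-coding TSS within 100 kb, and the mean number per member was compared with 100000 random lists of the same size matched on 10 groups of territory length, two-sided. The smallest p these permutations can give is 2e-05. Distal peaks 12.5 kb or less apart were joined to clusters, ranked by summed width times fold within the replicated list, and genes nearest to the top 500 were compared with genes nearest to any other cluster by two-sided Fisher's exact tests. Sequence matches on either strand in the central 500 bp of distal peaks were compared with windows 5 kb to each side that overlapped no pooled peak, matched on GC in bins of 2 percentage points. Adjusted p-values are Benjamini-Hochberg values over the lists or over the sequences, called at 0.05.

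Genes were named by a rule fixed beforehand. It took up to 4 members per list with the highest fold at a TSS, every marked member up to 6 for lists of other organs, and up to 4 unmarked members per list in list order. It also took the nearest genes of the 10 strongest peaks and the 20 highest clusters, the 10 genes with the most distal peaks, the 5 strongest peaks of each replicate alone, and the loci of Nkx2-1, Sftpc, Foxf1 and Tbx4. Members near the top 500 clusters, Aldh1a1, Kdr, the Hox genes and the widest peaks fall outside it and were chosen after their values or with their own test.

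The alternatives were stricter or looser overlaps, equal numbers of peaks, −log10 q of at least 5, fold of at least 4, other TSS windows, protein-coding genes alone, the 5-prime-most TSS alone, the pooled list, each replicate list in place of the replicated list (leaving out the other replicate), a distal limit of 50 kb, matching on the TSS mark, other joining distances and rankings, windows of 200 bp, flanks not matched on GC and reversed sequences. Those added after seeing the data were replicated peaks overlapped in both replicate lists, flanks matched on GC and CpG count, windows of at most 20% repeats, and peaks per annotated TSS position on each chromosome.

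The code was tested on simulated data. Overlap calls differed from a direct count in 0 of 1200 intervals. Of lists planted at a 97% mark rate, 99.6% were called higher, of lists planted at a 5% rate 99.3% were called lower, and 1.46% of unchanged lists were called, all on 21938 genes. Lists planted at 4 times the distal peak count were called in 75% of cases and unchanged lists in 0.972%. All 400 planted clusters were recovered from 800 peaks. A sequence planted in 3% of windows rose by 2.82 percentage points over 39817 windows, and 0 of 21 others were called. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.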

Results

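Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the lung of mouse embryos at embryonic day 16.5, a stage at which branching airways, mesenchyme and vessels are present and the distal epithelium begins to differentiate. The samples form 1 group of 2 biological replicates, each prepared from lungs pooled across embryos of both sexes, so the comparisons are between the replicates, between gene groups and between genomic regions within the group. The peak lists hold no read counts, and the sequencing depth behind each value is unknown. Replicate 1 gave 105238 peaks covering 59.0 Mb and replicate 2 gave 66952 peaks covering 35.6 Mb of the assembled chromosomes. A list called on both replicates together held 85728 peaks, and the deposited list of replicated peaks held 70004, with a median width of 484 bp. Fold enrichments are the authors' value per peak and are compared only within a list. Intervals of shares are exact binomial 95% intervals. Those of odds ratios and of density ratios are 95% intervals by a normal approximation on the log scale. All of them cover counting error only.

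The strongest H3K27ac peaks were present in both replicates. The peak with the highest fold enrichment of the replicated list, 61.6, spanned 6999 bp at chromosome 5, 123133626 to 123140624 (mm10), over the long noncoding gene AI480526, with its midpoint 4433 bp from the nearest start of a coding gene, Rhof, a small Rho GTPase. Distances of peaks from genes are given from peak midpoints, whereas nearness to a TSS within 1000 bp is judged from peak ends. It overlapped peaks of fold 59.8 in replicate 1 and 52.7 in replicate 2. The promoter peak of Zfp143, a zinc finger activator, had a fold of 59.2 in the replicated list, 58.5 in replicate 1 and 46.6 in replicate 2. The promoter peak of Sp3, a zinc finger factor that binds GC boxes, had a fold of 57.0 in the replicated list, 54.6 in replicate 1 and 48.2 in replicate 2. The other 7 of the 10 strongest peaks were nearest to Tnrc18, Arrdc3, Nfib, Gpr19, Sirt4, Sp1 and Tpm4, with folds from 55.9 down to 51.2, and each overlapped a peak in both replicate lists. Of the replicate 2 peaks, 91.4% (91.2 to 91.6; 61173 of 66952) were overlapped by 1 bp or more by a replicate 1 peak, against a mean of 4.17% over 100 random placements. Of the replicate 1 peaks, 49.6% (49.3 to 50; 52249 of 105238) were overlapped by a replicate 2 peak, against 2.61% at random. The share depended on the strength of the peak. Ordered by p-value, 99.99% of the strongest 10% of replicate 1 peaks and 13.2% of the weakest 10% were overlapped in replicate 2. In the opposite direction these shares were 100% and 76.9%. Across 36988 pairs of peaks that overlapped one to one, the log2 fold enrichments of the replicates correlated with a Spearman rho of 0.694 and a Pearson r of 0.807. These correlations are across peaks, which are not independent replicates, and carry no p-value. Requiring a reciprocal overlap of at least 50% of both lengths lowered the share of replicate 2 peaks found in replicate 1 to 51.4% and of replicate 1 peaks found in replicate 2 to 32.7%, while the strongest 20000 peaks of each list gave 86.8% and 77.0%.

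**Figure D1:**
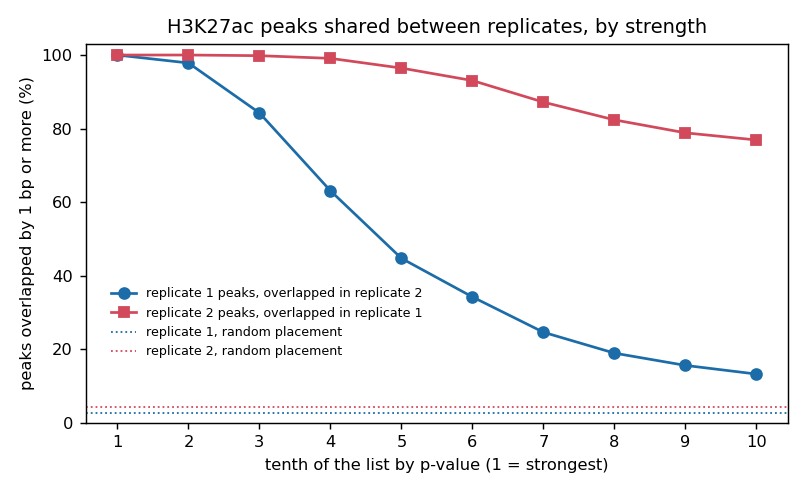
Percent of H3K27ac peaks overlapped by 1 bp or more in the other replicate (vertical axis) for each 10% of a replicate's list ordered by p-value (horizontal axis, 1 is the strongest). Blue circles are replicate 1 peaks (99.99% in the first 10%, 13.2% in the last), red squares are replicate 2 peaks (100% and 76.9%), and dotted lines are the means of random placements, 2.61% and 4.17%.

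The replicated list was a subset of the list called on both replicates together. All 70004 of its peaks stood unchanged in that list, of which they were 81.7%. Of the replicated peaks, 50172 (71.7%) overlapped a peak in both replicate lists, 17247 (24.6%) in replicate 1 alone, 1623 (2.32%) in replicate 2 alone and 962 (1.37%) in neither. Peaks supported by both lists had a median fold of 5.55 and a median width of 634 bp, against 3.50 and 291 bp for those overlapped in replicate 1 alone. An overlap of at least 50% of the peak's length in both replicate lists held for 37922 peaks (54.2%), so that this rule does not describe how the list was made. The replicated list was used as deposited, and the mark of each gene group is given in the replicate lists as well.

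TSS-proximal peaks, those within 1000 bp of an annotated transcription start site (TSS), were the strongest class. They were 31.4% of the replicated peaks (31.1 to 31.7; 21984 peaks), 3.78 times the 8.30% ± 0.0985 (SD of 100 random placements), and had a median fold of 6.37. Intronic peaks were 40% (39.6 to 40.4) with a median fold of 4.19, against 39.2% of random placements. Exonic peaks were 3.46% against 3.15% at random. Intergenic peaks were 25.1% (24.8 to 25.5) against 49.3% at random, with a median fold of 4.25. The 48020 peaks farther than 1000 bp from every TSS, called distal here, lay a median of 21.2 kb from the nearest start of a protein-coding gene, and 85.4% of them lay within 100 kb of one. The TSS-proximal share was 26.0% in replicate 1 and 33.3% in replicate 2.

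At the 4 loci chosen for a full description, the widest peak covered the promoter or the first part of the gene. Nkx2-1 (ENSMUSG00000001496.15, chromosome 12, 56531958 to 56536908, minus strand), the transcription factor that specifies lung and thyroid, had 11 replicated peaks within its body and 20 kb on each side. The widest, 6281 bp at 56532854 to 56539134 with a fold of 18.9, covered most of the gene including its TSS. A row of 9 peaks reached downstream from 56532638 to 56510988. One lay in an Nkx2-1 exon (56532065 to 56532638, fold 8.94) and one between the genes (56527686 to 56531975, 11.5, near a TSS of Sfta3-ps), while 6 lay in introns of Sfta3-ps at 56525518 to 56527507 (14.4), 56523731 to 56525272 (10), 56522141 to 56523530 (10), 56519023 to 56521945 (7.53), 56517395 to 56518942 (9.56) and 56514936 to 56515590 (4.66). The last of the row, 56510988 to 56512159, had a fold of 4.10 and lay at a TSS of Sfta3-ps. On the upstream side a single weak peak, 56541400 to 56541866 with a fold of 2.24, was overlapped in replicate 1 and not in replicate 2.

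Sftpc (ENSMUSG00000022097.4, chromosome 14, 70520949 to 70524081, minus strand), which encodes a surfactant protein of alveolar type II cells, lay among 12 replicated peaks. A 4939 bp peak at 70519049 to 70523987 with a fold of 13.5 covered nearly the whole gene, and a 516 bp peak at 70524179 to 70524694 with a fold of 4.52 had its midpoint 356 bp from the TSS. Upstream peaks between genes stood at 70525178 to 70525579 (fold 3.10), 70526383 to 70527144 (5.23), 70527260 to 70528080 (4.60) and 70529387 to 70529600 (2.92). The neighbouring gene Lgi3 had TSS-proximal peaks at 70529746 to 70529930 (3.81) and 70530102 to 70532025, the latter with a fold of 15.2, and intronic peaks at 70532310 to 70532639 (4.75) and 70534519 to 70534804 (3.70). A peak at 70515717 to 70516050 (3.0) lay in an intron of Bmp1 and another at 70541062 to 70541422 (3.24) lay between genes near Reep4.

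Foxf1 (ENSMUSG00000042812.5, chromosome 8, 121084386 to 121088144, plus strand), a transcription factor of lung mesenchyme and endothelium, carried the strongest peak of the 4 loci, 5806 bp at 121081339 to 121087144 with a fold of 27.9. A 2716 bp peak followed at 121088928 to 121091643 (fold 8.28) and a 605 bp peak at 121092092 to 121092696 (3.32). Upstream, 8 peaks stood between 121073111 and 121081155, at 121073111 to 121073327 (3.36), 121073442 to 121073883 (4.09), 121074069 to 121074388 (3.88), 121074549 to 121074935 (2.42), 121075504 to 121075756 (3.10), 121075951 to 121076275 (2.88), 121079226 to 121079710 (3.54) and 121080578 to 121081155 (3.42), all inside the long annotated transcript Gm20388. The TSS peak of the neighbour Mthfsd, 121107887 to 121108337, had a fold of 5.86. Tbx4 (ENSMUSG00000000094.12, chromosome 11, 85886422 to 85916097, plus strand), a T-box factor of lung mesenchyme and hindlimb, had 3 replicated peaks. They were a promoter peak at 85885719 to 85887083 (fold 11), an 8554 bp peak at 85887855 to 85896408 over the first part of the gene (13.3), and a 221 bp peak downstream at 85917255 to 85917475 (3.59).

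**Figure D2:**
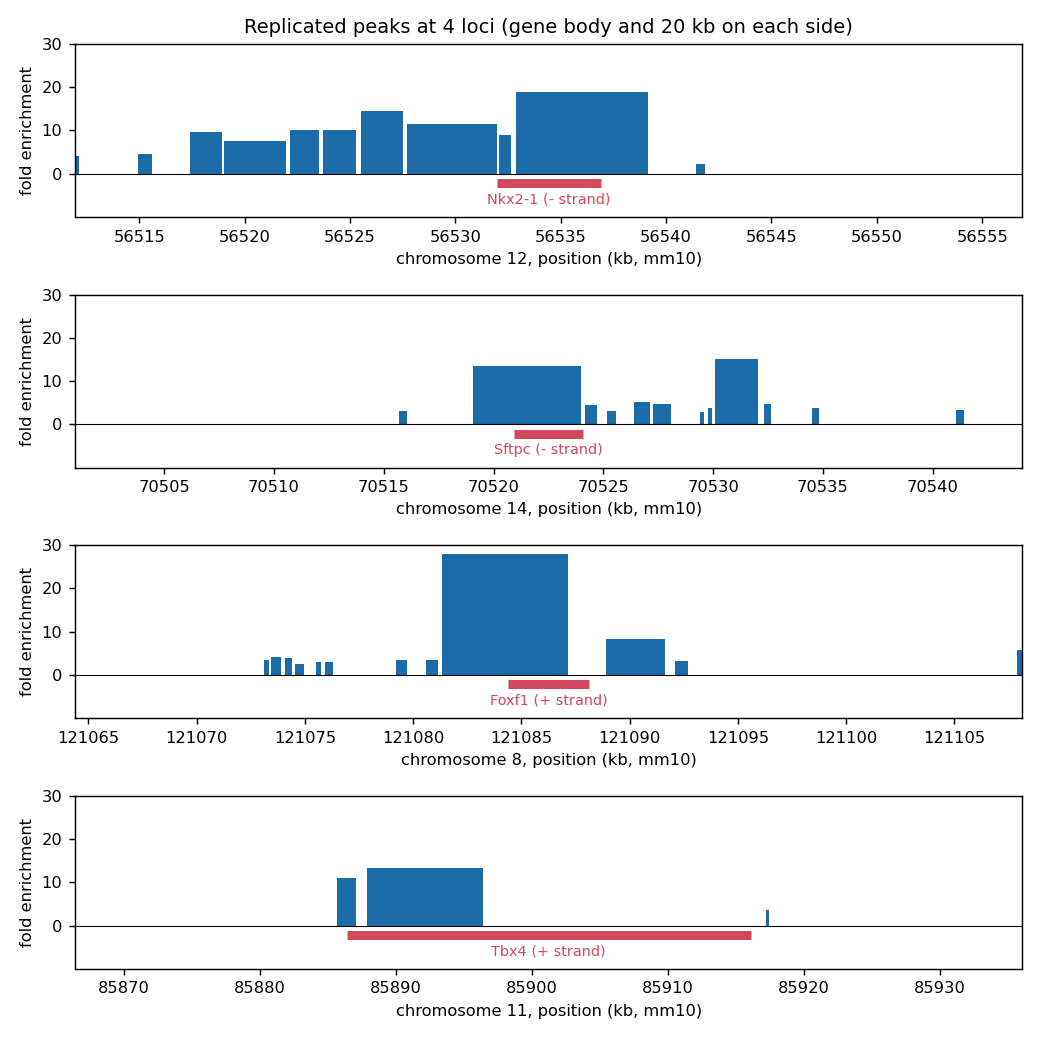
Replicated H3K27ac peaks (blue bars, from peak start to peak end in kb on mm10, height the authors' fold enrichment) over the bodies (red, with strand) and 20 kb on each side of Nkx2-1, Sftpc, Foxf1 and Tbx4. The highest peaks have folds of 18.9 at Nkx2-1, 15.2 at the Sftpc locus (the Lgi3 promoter), 27.9 at Foxf1 and 13.3 at Tbx4.

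Transcription factors of lung epithelium and genes of lung mesenchyme and vessels carried H3K27ac near an annotated TSS. Genes of brain, liver and the other gut organs rarely did. Over all protein-coding genes, 11922 of 21938 (54.3%, 53.7 to 55.0) had a replicated peak within 1000 bp of a TSS and are called marked. The counts were 12628 in replicate 1 and 11277 in replicate 2, with 11180 genes marked in both lists, 1448 in replicate 1 alone and 97 in replicate 2 alone. Any annotated TSS of a gene counts, so a marked TSS can lie far inside it. The Pecam1 peak (106657477 to 106662890) lay near the end of its gene (106654217 to 106750628, minus strand). The Mylk peak (34898053 to 34901530) lay well inside its gene (34745210 to 35002420, plus strand). Each of 27 gene lists fixed before the data were examined was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. A higher marked share was called for 13 lists and a lower one for 8.

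The transcription factors of lung epithelium were marked in 22 of 22 cases (adjusted exact p = 4.78e-05), in both replicate lists as well. The highest folds were at Foxp1 (32.2) and Foxp2 (25.8), forkhead repressors of the lung epithelium, Id2 (23.8), an inhibitor of helix-loop-helix factors, and Foxa2 (21.5), a forkhead factor of foregut endoderm. General epithelial genes were marked in 14 of 16 cases (adjusted exact p = 0.0155), with folds of 16.9 and 16.5 at the keratin genes Krt7 and Krt19, 15.5 at Esrp1, an epithelial splicing regulator, and 14.6 at Spint2, a protease inhibitor, while Grhl1 and Tacstd2 were unmarked. Genes of surfactant lipid metabolism were marked in 15 of 16 cases (adjusted exact p = 0.00313), led by Chka (23.9), a choline kinase, the desaturase gene Scd2 (23.4), Hmgcs1 (22.6) and the acyltransferase gene Lpcat1 (19.1). Scd1 was unmarked. Alveolar epithelial genes were marked in 13 of 18 cases, a share not called (adjusted exact p = 0.164), and in 14 of 18 in each replicate list, where the replicate 2 list passed the test (adjusted p = 0.0360). Among them were the tight junction gene Cldn18 (23.3), Lpcat1, the fatty acid synthase gene Fasn (17.8) and Sftpc (13.5). The surfactant protein genes Sftpa1 and Sftpd, the type I cell gene Pdpn and the water channel gene Aqp5 were unmarked, though Sftpd was marked in the replicate 2 list (fold 3.49). Airway epithelial genes were marked in 6 of 18 cases (adjusted exact p = 0.109), with folds of 39.5 at Rfx3 and 4.80 at Foxj1, both regulators of cilia, 8.88 at Cyp2f2, a cytochrome P450 of club cells, and 4.75 at Aldh1a7. Cyp2f2 was unmarked in the replicate 2 list. The secretoglobin genes Scgb1a1, Scgb3a2 and Scgb3a1 and the basal cell gene Trp63 were unmarked. The airway share was 8 of 18 in replicate 1 and 3 of 18 in replicate 2, and in replicate 2 it was called lower than that of other genes (adjusted exact p = 0.00648).

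Lung mesenchymal genes were marked in 21 of 22 cases (adjusted exact p = 2.17e-04). Folds were 28.3 at the homeobox gene Meis1, 27.9 at Foxf1, and 21.3 and 21.1 at the T-box genes Tbx3 and Tbx2, and Twist1 was the unmarked member. Smooth muscle genes were marked in 14 of 16 cases (adjusted exact p = 0.0155), with folds of 25.4 at Smtn, 18.9 at Srf, the serum response factor gene, 14.1 at the tropomyosin gene Tpm1 and 13 at Mylk, the myosin light chain kinase gene. Cnn1 and Synpo2 were unmarked. With peaks of −log10 q of at least 5 alone, the smooth muscle share of 75% was no longer called (adjusted exact p = 0.0544). Endothelial genes were marked in 20 of 20 cases (adjusted exact p = 7.94e-05), led by the adhesion genes Esam (15.5) and Pecam1 (12.3) and the ETS factor genes Ets1 (15.4) and Fli1 (10.2). Of the mesothelial genes 2 of 10 were marked, Podxl (6.24) and Msln (4.95), and Wt1, Upk3b, Lrrn4 and Aldh1a2 were unmarked. That share was not called (adjusted exact p = 0.0601) but was called lower with the list of both replicates pooled (20.0%, adjusted p = 0.0326).

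Most of the listed hedgehog, FGF, BMP and TGF-beta, and Notch genes were marked, and the Wnt and retinoic acid lists were not called. Each pathway list is a short choice of genes and not the whole pathway. Some of these genes, such as Id2, also stand in a lung list. All 12 listed hedgehog genes were marked (adjusted exact p = 0.00167), with folds of 27.9 at the receptor gene Ptch1, 23.3 at Gli3, 20.0 at Smo and 18.1 at Gas1. All 15 listed FGF pathway genes were marked (adjusted exact p = 4.34e-04), with 40.5 at Spry2, 35.7 at Dusp6 and 34.4 at Spred1, all feedback inhibitors, and 26.6 at the receptor gene Fgfr2. Of the BMP and TGF-beta genes 14 of 16 were marked (adjusted exact p = 0.0155), with 36.2 at Id3, 28.2 at the inhibitory Smad gene Smad7, 24.1 at Id1 and 23.8 at the receptor gene Tgfbr2, while Bmp2 and Grem1 were unmarked. Of the Notch genes 13 of 14 were marked (adjusted exact p = 0.00963), with 28.5 at Rbpj, 27.2 at Hes1, 24.8 at Lfng and 24.4 at Jag1, and Hey2 was unmarked. Hypoxia and angiogenesis genes were marked in 12 of 12 cases (adjusted exact p = 0.00167), led by Hif3a (43.8), the co-receptor gene Nrp1 (26.6), Hif1a (22.8) and Vegfa (16.0). Cell cycle genes were marked in 14 of 14 cases (adjusted exact p = 6.37e-04), with 25.8 at Birc5, 24.8 at Ccnd1, 17.2 at Aurkb and 15.1 at Cdk1. Housekeeping genes were marked in 16 of 16 cases (adjusted exact p = 2.75e-04), with 48.5 at Actb, 43.5 at Ywhaz, 34.1 at Polr2a and 29.1 at Tuba1b. Wnt pathway genes were marked in 12 of 16 cases, which was not called (adjusted exact p = 0.142), and Axin2, a negative feedback target, had a fold of 48.1, Fzd2 30.1, Ctnnb1 16.4 and Lgr4 14.8, against no mark at Lgr5, Notum, Rspo2 and Sfrp1. Retinoic acid genes were marked in 7 of 14 cases (adjusted exact p = 0.793). The receptor genes Rarg (39.9), Rara (23.0) and Rxra (20.0), the reductase gene Dhrs3 (12.6) and the synthesis gene Aldh1a1 (4.39) were marked, and Aldh1a2, Aldh1a3, Cyp26a1 and Cyp26b1 were not.

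Most lists of other organs and lineages were marked less often than other genes. None of 16 brain genes was marked (adjusted exact p = 4.78e-05), with Neurod1, Neurod2, Neurod6 and Foxg1 the first 4 of the list, and none of 14 genes of thyroid, pancreas and gut (adjusted p = 1.15e-04), among them Pax8, Tg, Tpo and Tshr. Of 16 liver genes 1 was marked (adjusted exact p = 4.34e-04), Apoh (8.10), at a peak also within 1000 bp of a TSS of Prkca. Of 14 germline and pluripotency genes 1 was marked (adjusted exact p = 0.00134), Dazl (5.57). Erythroid genes were marked in 3 of 14 cases (adjusted exact p = 0.0219), at the regulators Tal1 (7.05), Klf1 (5.46) and Nfe2 (3.65), and the globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 were unmarked. Neural crest and neuronal genes were marked in 2 of 12 cases (adjusted exact p = 0.0219), Erbb3 (22.7) and Phox2a (11.1). Myeloid genes were marked in 4 of 16 cases (adjusted exact p = 0.0293), Runx1 (16.2), Fcer1g (4.15), Spi1 (4.06) and Mrc1 (3.59), and this call did not hold in the replicate 1 list (5 of 16, adjusted p = 0.0541) or with a window of 2500 bp (31.3%, adjusted p = 0.0912). Cardiac muscle genes were marked in 2 of 12 cases (adjusted exact p = 0.0219), Myl4 (13) and Myh7 (11), the former at a peak shared with Cdc27, and in 5 of 12 in replicate 1 (adjusted p = 0.396) against 2 of 12 in replicate 2 (adjusted p = 0.0227). With the window of 2500 bp their share of 25% was not called either (adjusted exact p = 0.0513). Skeletal muscle genes were marked in 3 of 12 cases, Mylpf (10.8), Actn3 (3.71) and Tnnt3 (3.60), a share not called (adjusted exact p = 0.0573) but called lower in replicate 1 (3 of 12, adjusted p = 0.0492) and in replicate 2 (2 of 12, adjusted p = 0.0227).

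**Figure D3:**
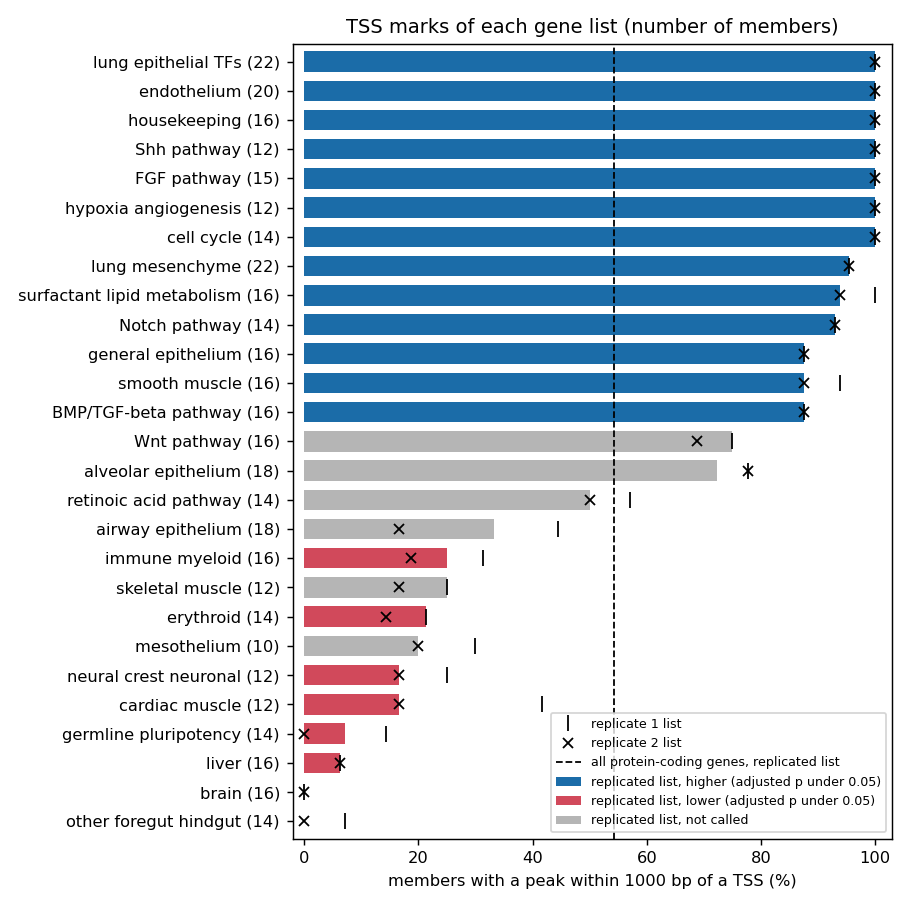
Percent of the members of each gene list with a replicated H3K27ac peak within 1000 bp of a TSS (horizontal axis, bars), with the number of members in parentheses, the percent in the replicate 1 list (vertical tick) and in the replicate 2 list (cross), and the 54.3% of all protein-coding genes (dashed line). Blue bars are the 13 lists called higher, red bars the 8 called lower (2 of them at 0%) and grey bars the 6 not called.

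More distal peaks than in random lists were counted for 10 gene lists and fewer for 3, and most of these calls ended when random lists were also matched on the TSS mark. Members of the BMP and TGF-beta list had 12.1 distal peaks each on average within 100 kb by nearest TSS, 3.72 times the mean of random lists of the same size matched on territory length (adjusted permutation p = 0.00162), with 38 at Tgfbr2 and 35 at Smad7. Endothelial genes had 10.1 distal peaks each against 2.82 (3.57 times, adjusted permutation p = 0.00162), with 37 at Kdr, 30 at Ets1, 19 at Fli1 and 17 at Pecam1. Apart from Kdr, the members given here are those with more distal peaks among the members named above for their folds at a TSS. Others named above had few, such as Id3 (4), Foxp2 (4), Esam (1), Srf (0) and Tbx2 (0). Members not named can have more distal peaks. FGF pathway genes had 12.5 against 4.04 (3.09 times, adjusted permutation p = 0.00522), with 48 at Fgfr2 and 21 at Spry2. Lung epithelial transcription factors had 11.8 against 4.90 (2.40 times, adjusted permutation p = 0.00810), with 59 at Foxp1 and 29 at Foxa2. The other lists called higher were general epithelium (3.33 times, adjusted permutation p = 0.00810), smooth muscle (3.18 times, adjusted p = 0.0130, with 38 at Mylk), alveolar epithelium (2.92 times, adjusted p = 0.00879, with 14 at Cldn18), Notch (2.63 times, adjusted p = 0.0295, with 25 at Hes1), Wnt (2.41 times, adjusted p = 0.0235, with 25 at Axin2) and lung mesenchyme (2.36 times, adjusted p = 0.0130, with 25 at Tbx3 and 12 at Foxf1). Fewer distal peaks than in random lists were counted for brain (0.0829 times, adjusted permutation p = 0.00810), neural crest and neuronal genes (0.0940 times, adjusted p = 0.0295) and the other gut organs (0.121 times, adjusted p = 0.0235). The neural crest call ended with a limit of 50 kb, with −log10 q of at least 5, with peaks overlapped in both replicate lists and in the replicate 2 list (0.236 times, adjusted permutation p = 0.175). The call of the other gut organs ended with −log10 q of at least 5, in the pooled list, with peaks overlapped in both replicate lists and in the replicate 1 list (0.333 times, adjusted permutation p = 0.100), and the Wnt call ended with a limit of 50 kb.

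The remaining 14 lists were not called. The hedgehog list, with 32 distal peaks at Ptch1, had 2.29 times the random mean (adjusted permutation p = 0.0768) but was called higher with a limit of 50 kb (2.83, adjusted p = 0.0313) and in the lists of replicate 1 (2.36, adjusted p = 0.0413) and replicate 2 (2.66, adjusted p = 0.0444). The ratios of the others were 2.08 for hypoxia and angiogenesis, 1.96 for surfactant lipid metabolism, 1.74 for retinoic acid, 1.5 for cell cycle, 1.45 for mesothelium, 1.41 for housekeeping, 1.41 for airway epithelium, 1.28 for myeloid, 0.822 for germline and pluripotency, 0.612 for liver, 0.509 for erythroid, 0.414 for cardiac muscle and 0.279 for skeletal muscle genes. The tests were two-sided permutation tests on 100000 random lists with Benjamini-Hochberg adjustment over 27 lists. When the random lists were also matched on whether each gene's TSS was marked, 3 of the 10 higher lists kept their call (general epithelium, endothelium, and BMP and TGF-beta) and none of the 3 lower lists did. In that setting the lists that kept it stood at 2.73, 2.37 and 2.84 times, and those that lost it ranged from 2.35 for alveolar epithelium (adjusted permutation p = 0.0525), 2.26 for smooth muscle (adjusted p = 0.0827), 2.05 for FGF (adjusted p = 0.0525) and 1.98 for Wnt (adjusted p = 0.0931) down to 1.82 for Notch (adjusted p = 0.173), 1.63 for lung mesenchyme (adjusted p = 0.167) and 1.58 for lung epithelial transcription factors (adjusted p = 0.157). Over single genes, the most distal peaks were nearest to Bcas3 (91), Mecom (78), a zinc finger regulator, Gse1 (63), 2010111I01Rik (62), Elmo1 (59), Foxp1 (59), Rbms1 (56), Tns3 (56), Arid5b (54) and Nav2 (54), against a mean of 1.87 per protein-coding gene.

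**Figure D4:**
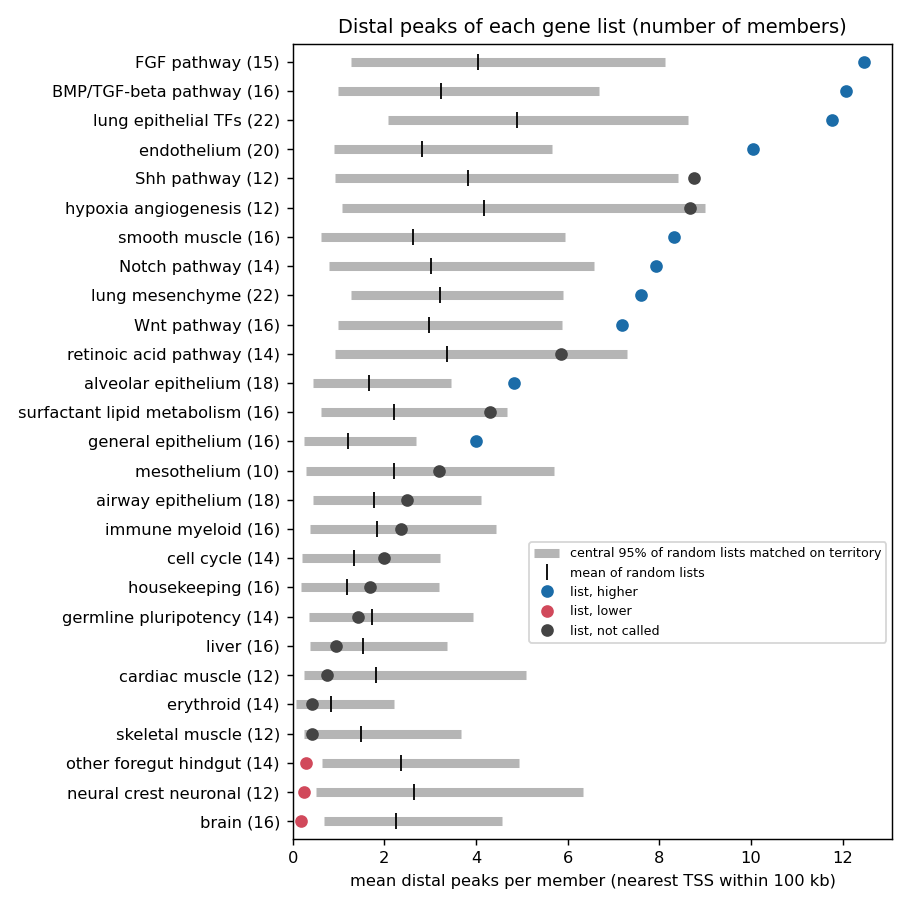
Mean number of distal replicated H3K27ac peaks per member of each gene list (points, horizontal axis), assigned to the nearest protein-coding TSS within 100 kb, with the mean (tick) and central 95% (grey bar) of random lists matched on territory length. Blue points are the 10 lists called higher (FGF pathway highest at 12.5), red points the 3 called lower (brain lowest at 0.188) and dark grey points those not called.

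The largest clusters of distal peaks lay over or near Nfib, Fmod with Btg2, and the T-box genes Tbx2 and Tbx4. The first of 17585 clusters, formed from distal peaks 12.5 kb or less apart and ranked by summed width times fold, held 80 peaks over 276.5 kb of chromosome 4 (82265765 to 82542264) across Nfib, a nuclear factor I gene needed for lung maturation. The next touched the bodies of Fmod, a proteoglycan gene, and Btg2, with 34 peaks over 147 kb. The cluster at rank 3 held 43 peaks within Bcas3 on chromosome 11 (85663494 to 85807878), and its edge lay 24.7 kb from Tbx2 and 78.5 kb from Tbx4. Ranks 4 to 10 were nearest to Irf2bp2, Sik1, 1700001O22Rik, the collagen IV gene Col4a1, Chd2, Zfp36l1 and Morn1, the last also touching Ski. Further clusters among the first 20 were nearest to Zfp36l1 (2 more), Irf2bpl, Bahcc1, Smad7, Tex44, Ddc, Ube2v1, Ly86 and the non-muscle myosin gene Myh9. Of all clusters 43.2% were single peaks, the top 100 held 11.2% of the summed signal and the top 500 held 29.7%.

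Among genes nearest to any cluster, 5.74% were nearest to one of the top 500, and 5 lists stood above this by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 27 lists. They were BMP and TGF-beta (5 of 14 members, Id1, Smad6, Smad7, Tgfbi and Tgfbr2, adjusted exact p = 0.0213), hedgehog (4 of 11, Ptch1, Gli2, Sufu and Boc, adjusted p = 0.0344), Notch (4 of 13, Notch1, Notch2, Hes1 and Dll4, adjusted p = 0.0454), lung epithelial transcription factors (5 of 22, Nkx2-1, Foxa1, Foxa2, Sox9 and Hopx, adjusted p = 0.0474) and surfactant lipid metabolism (4 of 15, Fasn, Scd2, Lpcat1 and Chka, adjusted p = 0.0474). These members are named because of their values. The remaining 22 lists were not called. Unlike the test of distal peaks, this test set no distance limit and was not matched on territory length. A contribution of territory length to these calls is therefore not removed. The calls depended on how clusters were made: none of the 5 remained when peaks were joined at 5000 bp, when the top 200 clusters were used or with −log10 q of at least 5, and only BMP and TGF-beta remained when clusters were ranked by covered width or made from replicate 2 alone.

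Sequences of several transcription factor families were more frequent in distal peaks than beside them. The palindrome of the NFI family, to which Nfib belongs, was present in the central 500 bp of 0.866% of distal peaks against 0.311% of GC-matched flanking windows, an odds ratio of 2.80 (2.31 to 3.39, adjusted exact p = 1.51e-28). MEF2 sites, bound by factors of muscle and endothelium, had an odds ratio of 1.78 (1.55 to 2.05), ETS sites (CCGGAARY), bound by Ets1, Fli1 and other ETS factors, 1.69 (1.55 to 1.86), TEAD sites (RCATTCC), read out by the Hippo pathway, 1.46 (1.41 to 1.51), FOX sites (TRTTTAC) 1.39 (1.34 to 1.45) and NKX2 sites (CACTTRA) 1.20 (1.16 to 1.25, adjusted exact p = 1.5e-20). These comparisons used 46302 windows on each side, two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 22 sequences, of which 13 were called higher, 2 lower and 7 not called. Of the 13, 7 kept the call in the central 200 bp, where GATA, AP-1, C/EBP, GLI, the CArG box and SP/KLF lost it, and 8 kept it in windows of at most 20% repeats, where the first 5 of these lost it. GLI also lost the call in the replicate 2 list (1.15).

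The same sequences were read backwards as a control of equal base composition. Reversal does not keep CpG pairs: the ETS sequence loses its CpG (YRAAGGCC), and the NFI sequence gains some. Both directions of SP/KLF hold GGGCGGG, so the control cannot weigh SP/KLF. Backward odds ratios were lower for MEF2 (1.11), ETS (1.15), TEAD (0.992), FOX (1.06), NKX2 (1.1) and GATA (0.987 against 1.05). Their 95% intervals did not overlap those of the forward sequences. For the others called higher the intervals overlapped: C/EBP 1.68 forward and 1.40 backwards, SP/KLF 1.36 and 1.37, SOX 1.25 and 1.33, GLI 1.24 and 1.00, AP-1 1.13 and 1.07, the CArG box 1.13 and 1.09, and NFI, whose backward sequence was rare, 2.80 and 1.75 (0.750 to 4.08). NFY sites (0.805, 0.777 to 0.834) and RUNX sites (0.955, 0.917 to 0.994) were less frequent in peaks, but so were their backward sequences. These had 0.913 (0.879 to 0.949) for NFY and 0.940 (0.895 to 0.988) for RUNX. The forward and backward intervals overlapped for RUNX and not for NFY. The GATA odds ratio turned to 0.805 (adjusted exact p = 4.75e-74) when flanks were not matched on GC, SP/KLF to 0.929 (adjusted p = 0.456) in the central 200 bp, and RUNX to 1.08 (adjusted p = 0.00760) in windows of at most 20% repeats, a setting added after seeing the data.

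**Figure D5:**
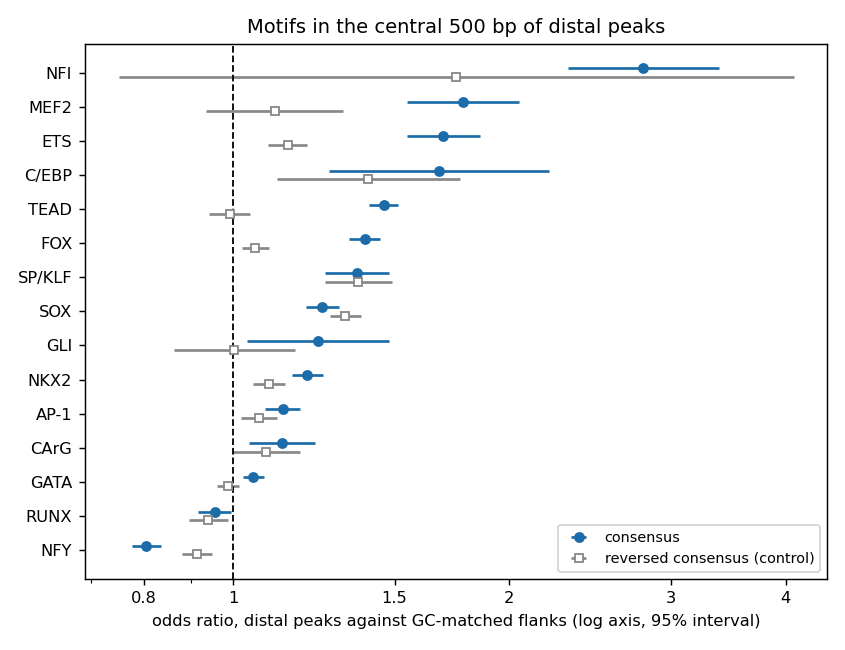
Odds ratios (log axis) of the 15 called sequences in the central 500 bp of distal replicated peaks against GC-matched flanking windows, with 95% intervals. Blue circles are the consensus sequences, from 2.80 for NFI down to 0.805 for NFY, and grey squares the reversed sequences used as a control.

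Peaks found in one replicate list alone were narrower, weaker and less often near a TSS than shared ones. The strongest peaks of replicate 1 without overlap in replicate 2 lay at the TSS of the histone gene Hist1h2ah (fold 11.2), in an intron of Dab2 (10.6), at Spdl1 (9.65), 15437 bp from Vcam1 (9.05) and at Zfp747 (9.05). In replicate 2 they lay at Dlc1 (7.38) and Acacb (7.12), in an intron of Egflam (6.55), 22548 bp from Bmf (6.47) and 6268 bp from Zmat2 (6.27). TSS-proximal peaks were 17.1% of the 52989 peaks found in replicate 1 alone and 35.0% of its shared peaks, an odds ratio of 0.384 by two-sided Fisher's exact test (p = 1e-300, the smallest value written). In replicate 2 they were 15.6% of 5779 peaks against 34.9% (odds ratio 0.343, exact p = 1.22e-220). Median widths were 243 bp alone and 611 bp shared in replicate 1, and 215 and 385 bp in replicate 2. These tests describe the peaks of each list and not a difference between the tissue pools.

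Chromosome 11, which carries Tbx2, Tbx4, Axin2 and the Hoxb genes, had the most H3K27ac peaks for its length, 43.5 per Mb of sequence, against 28.7 over all autosomes and 21.9 on chromosome 14, the lowest autosome. The X chromosome had 7.97 peaks per Mb, 0.278 times the autosomal density (95% interval 0.263 to 0.294), and the ratio was 0.296 in replicate 1 and 0.255 in replicate 2. Per annotated TSS position, a scale added after the data were seen, X had 0.277 peaks against 0.546 on autosomes, a ratio of 0.508 (95% interval 0.481 to 0.537), and chromosome 18 had the most (0.727) against 0.640 on chromosome 11. The Y chromosome held 3 peaks.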

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

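The tests of genes gained in replicate 1, of CpG content, and of repeats for FOX, ETS, TEAD and MEF2 alone, and the reading of shares of 16 genes as complete counts, were chosen after the result was seen, and the design holds 1 group, so no biological explanation was tested in this part.

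Of the 70013 replicated peaks, 9 lay on scaffolds outside the assembled chromosome sequences and entered no comparison, and the strongest of them, on an unlocalised chromosome 4 scaffold, had a fold of 45.3.

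The replicate 1 list held 105238 peaks and the replicate 2 list 66952. A lower sensitivity of the replicate 2 list for weak peaks is a candidate explanation: 99.99% of the strongest 10% of replicate 1 peaks were overlapped in replicate 2, and 13.2% of the weakest 10% were. The weakest 10% were also narrower (median 210 bp against 1436 bp), so the fall in overlap does not single out this explanation. Tissue of other organs in the replicate 1 pool stays open, since 7 of 79 genes of the heart, skeletal muscle, liver, brain, other gut and germline lists that were unmarked in replicate 2 were TSS-marked in replicate 1 (8.86%, 3.64 to 17.4), an interval that includes the 13.6% of other protein-coding genes (two-sided Fisher's exact p = 0.252), and other organs have no list. The highest share of a single list in replicate 1, 5 of 12 cardiac genes (41.7%, 15.2 to 72.3), did not decide it either, as a small admixture need not reach the 57.6% of all protein-coding genes. Sequencing depth, and the 2 further source files of replicate 1 against 1 of replicate 2, stay open and were not tested.

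Some genes of other lineages were TSS-marked in lung, 16 over the cardiac, skeletal muscle, erythroid, germline, myeloid, liver and neural lists, with Erbb3 (22.7), Runx1 (16.2) and Myl4 (13) the strongest. If weak peaks let in by the authors' threshold caused most of these marks, over 50% were predicted to be lost at −log10 q of at least 5. Of the 16, 4 (Nfe2, Mrc1, Spi1 and Tnnt3), or 25%, were lost (20.0% to 26.7% leaving out 1 gene, a range set by the count alone). Among other marked genes 9.16% were lost (odds ratio 3.30, two-sided Fisher's exact p = 0.0527). Fcer1g (−log10 q 5.30) and Actn3 (5.61) passed the threshold narrowly. These counts do not decide how far weak peaks contribute. The promoter of a neighbouring gene was predicted to lie at over 50% of these peaks. The peaks of 4 others (Myl4, Apoh, Actn3 and Mylpf), again 25%, lay within 1000 bp of a TSS of another protein-coding gene. The share among other marked genes was not computed and TSSs of noncoding genes were not counted, so this count does not decide it either. Together these counts cover 8 of the 16 marks. Each of the 2 causes stays open for its own 4 genes, and a binomial interval for a wider class of such genes (7.27 to 52.4) would include 50%. What causes the other 8 marks stays open. Dazl, 1 of these 8, was unmarked in the replicate 2 list, as were Nfe2, Mrc1 and Actn3. The Phox2a peak (101821681 to 101822946) lay over the end of its gene (101818313 to 101822726, plus strand). Resident cells of other types were not tested, since the data hold no sorted cells.

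Sequences of 6 factor families, NKX2, FOX, GATA, ETS, TEAD and MEF2, had odds ratios above those of their reversed controls in distal peaks. CpG content left unequal by GC matching is argued against for 5 of them: with flanks matched on GC and CpG count the lowest odds ratio of NKX2, FOX, ETS, TEAD and MEF2 was 1.21, for NKX2 (1.16 to 1.25). Repeats in the flanking windows are argued against only as the whole cause for FOX, ETS, TEAD and MEF2, singled out after these values were seen. Their lowest odds ratio in windows of at most 20% repeats was 1.34, for TEAD (1.28 to 1.40). There ETS fell from 1.69 to 1.52, TEAD from 1.46 and MEF2 from 1.78 to 1.47, while FOX stood at 1.39 before and 1.41 after. A part owed to repeats therefore stays open. For NKX2 the same windows gave 1.12 (1.06 to 1.17), an interval that includes the bound of 1.1, so repeats stay open there. GATA was not weighed, since its odds ratio of 1.05 was below that bound before any correction.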

How the results depend on the processing

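Replicated peaks overlapped in both replicate lists, matching on GC and CpG, windows of at most 20% repeats, and peaks per annotated TSS position were alternatives chosen after seeing the data. Over 95 results and 712 alternatives, 552 changed little, meaning that a test kept its direction and side of the threshold, a share, ratio or correlation stayed within its interval, or a count or the share of signal in the top clusters stayed within 1.5 times, while 61 moved, 71 were no longer called, 16 became called and 12 turned direction. These totals include the reversed sequences, which are a control. For them a kept call does not show stability, and a lost or turned call does not show dependence on the processing. The causes were not tested. Depth is unknown, so no result could be set against it. No paired analysis was possible because the samples form 1 group.

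The number of marked genes stayed between 10827 and 12628, and the lists called for TSS marks between 12 and 14 higher and 6 and 10 lower. The 5-prime-most TSS alone was applied to the number of marked genes and not to the lists. Whether the list calls depend on TSSs inside genes was therefore not tested. The overlap of replicate 2 peaks in replicate 1 and of replicate 1 peaks in replicate 2 was 86.3% and 34.9% for at least 50% of the peak, 51.4% and 32.7% for reciprocal 50%, 96.5% and 50.4% at −log10 q of at least 5, 83.3% and 68.4% for equal numbers by p, and 86.8% and 77.0% for the strongest 20000. The correlation of fold was 0.748 with reciprocal 50% and 0.727 at −log10 q of at least 5. The TSS-proximal share was 27.7% with a window of 500 bp, 39.6% with 2500 bp, 27.5% for protein-coding genes, 39.6% at −log10 q of at least 5, 28.8% in the pooled list, 35.8% for peaks overlapped in both lists, and 26.0% to 33.3% leaving out 1 replicate. The density on X relative to autosomes was 0.262 at −log10 q of at least 5 and 0.255 to 0.296 leaving out 1 replicate, and 0.508 per annotated TSS position.

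For TSS marks, the airway list was called lower with 500 bp (27.8%), fold of at least 4 (22.2%), −log10 q of at least 5 (22.2%) and overlap in both lists (16.7%). Skeletal muscle was called lower with fold of at least 4 (8.33%), −log10 q of at least 5 (16.7%), the pooled list (25%) and overlap in both lists (16.7%), and mesothelium in the pooled list (20.0%). Calls were lost for myeloid (31.3%) and cardiac genes (25%) with 2500 bp and for smooth muscle (75%) at −log10 q of at least 5. The retinoic acid list, never called, stood above other genes with 2500 bp (64.3% against 56.1%), fold of at least 4 (50% against 49.8%) and −log10 q of at least 5 (50% against 49.4%). Leaving out 1 replicate gave 77.8% for the alveolar list both times, 16.7% to 44.4% for airway, 16.7% to 25% for skeletal muscle, 18.8% to 31.3% for myeloid and 16.7% to 41.7% for cardiac genes.

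For distal peaks, matching also on the TSS mark left 3 lists called higher and 0 lower. Relative to random lists it gave 1.58 for lung epithelial transcription factors, 2.35 alveolar, 1.63 mesenchyme, 2.26 smooth muscle, 2.05 FGF, 1.98 Wnt, 1.82 Notch, 0.265 neural crest, 0.215 brain and 0.333 other gut, with turned directions for cardiac muscle (1.01), liver (1.08), germline (1.54) and housekeeping (0.944), none of them called. A limit of 50 kb ended the calls of neural crest (0.117) and Wnt (2.05) and made hedgehog called (2.83). At −log10 q of at least 5, 1 list was called lower (neural crest 0.0593 and other gut 0.113 were lost), as with overlap in both lists (0.0935 and 0.134), and the pooled list lost other gut (0.236). Leaving out 1 replicate gave 0.0966 to 0.236 for neural crest, 0.128 to 0.333 for other gut and 2.36 to 2.66 for hedgehog, called both times.

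The 5 lists called at clusters became 0 with joining at 5000 bp, with the top 200 and at −log10 q of at least 5, 1 by covered width and with overlap in both lists, and 1 to 2 leaving out 1 replicate. Of the 13 sequences called higher, 7 were called in the central 200 bp, without GATA, AP-1, C/EBP, GLI, CArG and SP/KLF, and 8 in windows of at most 20% repeats, without GATA, AP-1, C/EBP, GLI and CArG. GATA and CArG lost the call without GC matching, and GLI lost it without replicate 1 (odds ratio 1.15 against 1.24) and with overlap in both lists (1.22). The 2 called lower became 4 without GC matching and 1 in windows of at most 20% repeats. Odds ratios turned for SP/KLF in the central 200 bp (0.929), GATA without GC matching (0.805), RUNX in windows of at most 20% repeats (1.08), and for the reversed sequences of GATA (0.987) and TEAD (0.992).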

Other observations

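Hox genes, which give positional identity along the body axis, were marked in a block of the A and B clusters. Of 39 Hox genes 12 had a replicated H3K27ac peak at a TSS, with folds of 21 at Hoxa1, 20.2 at Hoxb4, 18.8 at Hoxb5, 17.0 at Hoxa2, 16.5 at Hoxa4 and 14.3 at Hoxa5, a gene needed for lung development. Hoxb1, Hoxb8 and Hoxa7 were the unmarked members of these clusters in groups 1 to 8, and the C and D clusters had no marked gene. The hypothesis that paralog groups 1 to 8 are marked more often than groups 9 to 13 in embryonic lung was tested, and 12 of 23 against 0 of 16 genes were marked (two-sided Fisher's exact p = 3.72e-04), which is consistent with it. Neighbouring Hox genes share peaks and are not independent, so the p-value may be too small. Within groups 1 to 8, 12 of 15 genes of clusters A and B and 0 of 8 of clusters C and D were marked (two-sided Fisher's exact p = 3.37e-04).

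The widest replicated peak, 14865 bp at chromosome 11, 85832715 to 85847579, covered most of Tbx2, a mesenchymal T-box gene. It was followed by peaks of 11976 bp at Hoxb3, 11805 bp at Id3, 10449 bp at Zmynd8, 10428 bp within the noncoding gene Carmn near the microRNA gene Mir143, 9828 bp at Fam129b, 9443 bp in an intron of Notch1, 9289 bp at Fhod1, 9194 bp at Bcl9l and 9176 bp in an intron of Bcas3. Sensory receptor genes were nearly free of the mark. It was present at 6 of 1135 olfactory receptor genes (0.529%, 0.194 to 1.15), 1 of 329 vomeronasal receptor genes (0.304%) and 0 of 38 taste receptor genes, against 54.3% of all protein-coding genes, 34.3% of antisense genes (32.6 to 36.0) and 17.6% of lincRNA genes (16.6 to 18.6).

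On the X chromosome 342 of 948 protein-coding genes were marked (36.1%, 33.0 to 39.2), against 55.6% of autosomal genes (two-sided Fisher's exact odds ratio 0.450, p = 3.40e-32). The marked share of autosomal genes ran from 44.8% on chromosome 7 to 63.5% on chromosome 12.

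The division of Hox genes within groups 1 to 8 by cluster was tested only after the marks were seen, and the widest peaks, gene classes and chromosome comparison described here were chosen after the values were seen.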
